A study of Mus musculus with 2 samples.

How the data were processed

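The samples were 2 Visium libraries of brown adipose tissue from C57BL/6 mice, 1 from thermoneutral housing and 1 collected 4 days after a transient acute cold exposure, as the labels' treatment field gives it. Sections were prepared, stained, imaged and sequenced with the supplier's Visium protocol, per the labels' protocols. The deposited matrices hold counts, whole numbers of UMIs per gene and spot, not normalized, for 32285 genes. The submitters' processing notes name Space Ranger 1.3 and the mm10 build, and further settings are not given in the sources used here. The matrices are the filtered kind by their names, and the spots in them were taken as the spots over tissue. No doublet caller was run, since a spot can hold several cells. Spot positions and images were not used here.

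Gene symbols and identifiers are those of the deposited feature tables. Coordinates and strand came from the GENCODE release M21 annotation of mm10, in which 32158 of the 32285 identifiers were found. Symbols carried by more than 1 identifier (78 identifiers in all) were left out of lists, which removed Aldoa from the glycolysis list. Gyk and Mut were not found as symbols in the feature tables. Of the heat shock and ER stress list 9 of 10 genes could be used, and of the lymphatic endothelium list 5 of 6.

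UMIs were summed over all spots of a library and divided by the library's total to give CPM. A gene was measured when it had at least 50 UMIs over both libraries (12894 genes). Each CPM has an exact Poisson 95% interval, each ratio an exact conditional 95% interval, and each share of spots an exact Clopper-Pearson interval, all of which cover counting error only and not the variation between mice, sections or capture areas. A count of 0 was given a floor of 3 counts per library, which is 0.0746 CPM at thermoneutrality and 0.0943 CPM after cold, and a ratio against it is a bound. A gene counted as higher or lower by size when its ratio was at least 1.5-fold and its interval excluded 1. With 1 library per group no test was run and no p-value was computed.

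Before the data were examined, 37 gene lists for pathways, cell type markers and signs of tissue handling were fixed, along with the rule for named genes, the measures and most of the alternatives. For each list the median log2 ratio of its measured members is given with an interval from 1000 Poisson redraws of the counts and with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Members of a random list were drawn independently of each other. A percentile therefore takes no account of genes that vary together and is not a p-value. The named genes were the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM in 1 library and not mitochondrially encoded, up to 4 most abundant members and 2 members of largest absolute ratio in each list, and always Ucp1, Acly, Fasn, Acaca, Elovl6, Scd1, Scd2, Mlxipl and Srebf1. Regions are named by their 5 leading genes by fold over the other spots, among genes at 50 CPM or more. Genes outside this rule are said to have been named after their values were seen. Not every gene the rule takes is reported here.

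For measures across spots each spot was thinned at random, without replacement, to 5000 UMIs, and spots below that were left out. The Fano factor is the variance over the mean of a list's UMIs per spot, and Pearson's r was taken across spots within a library. Both stand beside values from multinomial draws that gave every spot the library's composition. Spots with over 1% of UMIs from the skeletal muscle list were called muscle spots (142 and 121, or 8.27% and 9.57%) and those with over 0.5% from the T and B cell lists lymphocyte-rich spots (6 and 0). Regions came from Leiden clustering at resolution 0.5 of spots scaled to 10000 UMIs and log-transformed, with 2000 variable genes, 30 principal components and 15 neighbours, run for each library on its own. Their list values are UMIs summed over the region's spots, per 5000.

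The alternatives were totals without mitochondrially encoded genes, edgeR's TMM factors, DESeq2's size factors, minima of 10 and 500 UMIs per gene, the mean of per-spot CPM in place of sums, only spots with at least 2000 UMIs, thinning to 2000 and 10000 UMIs, 15 principal components, resolutions of 0.3 and 1.0, and leaving out muscle and lymphocyte-rich spots. Alternatives added after seeing the data left out spots with over 0.02% of UMIs from the white adipocyte list, left out spots with over 0.1% from the muscle list, and limited the spot measures to spots with at most 1 white adipocyte UMI outside muscle and lymphocyte-rich spots.

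The ratio and interval code was tested on simulated counts for the 12894 genes of the cold-recovered against thermoneutral comparison, drawn from the libraries' own means and sizes. Of 50 genes set to each fold, the size rule called 100% at 2-fold, 100% at 4-fold, 96% at 0.5-fold and 98% at 0.25-fold, with median estimates of 2.00, 4.01, 0.496 and 0.255. Of 12694 genes left unchanged it called 0.488%, and the intervals covered the true ratio in 95.6%. The counts were Poisson draws, the model the intervals assume, so these rates check the code only. They leave out differences between mice, sections and tissue composition. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, the R packages being used for library scaling factors only (TMM factors 1.01 and 0.987).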

Results

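The series holds spatial transcriptomes of brown adipose tissue (BAT), the fat that burns fuel to make heat, from C57BL/6 mice. One library came from mice housed at thermoneutrality, the ambient temperature at which no extra heat production is needed. The other was collected 4 days after a transient acute exposure to cold and is called cold-recovered here. The labels do not say how many mice or sections lie behind a library, and the tissue of each library is called a section below. In the Visium assay polyadenylated RNA of a tissue section is captured on an array of barcoded spots, and a spot can hold parts of several cells of different types. The thermoneutral library held 40188784 unique molecular identifiers (UMIs) over 1718 spots, with a median of 21553.5 UMIs and 3814.5 genes per spot. The cold-recovered library held 31812236 UMIs over 1264 spots, with medians of 21953.5 UMIs and 3829 genes. Mitochondrially encoded transcripts took 37.2% and 36.3% of the UMIs. Each condition had 1 library and spots are not replicates, so no difference below has a replicate check, a p-value or a standard error. Intervals are 95% intervals that cover counting error only, exact except for list medians, whose intervals come from redrawn counts. Each comparison is between these libraries.

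The first question was how transcripts of de novo lipogenesis and of heat production differed between BAT at thermoneutrality and BAT 4 days after cold, since the series title names lipogenic brown adipocytes and thermogenic memory. Over the summed spots, fatty acid synthesis genes were higher in the cold-recovered section. Their 18 measured members together took 5104 CPM (UMIs per 1000000; interval 5082 to 5126) at thermoneutrality and 14858 CPM (14816 to 14901) after cold, 2.91-fold higher (2.90 to 2.93). Of these members 12 were higher by at least 1.5-fold with an interval excluding 1, none was lower by that rule and 6 were neither. The list's median log2 ratio was 1.16 (1.121 to 1.197), at the 100th percentile of 10000 random lists matched on expression, whose medians lay between -0.11 and 0.15 in 95% of draws. The median over all 12894 measured genes was -0.04, and by the same size rule 853 of them were higher and 1776 lower.

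Fasn, the fatty acid synthase (ENSMUSG00000025153, minus strand of chromosome 11, 120805846 to 120824547 in mm10), went from 427 to 4055 CPM, 9.50-fold higher (9.35 to 9.65). Acly, which splits cytosolic citrate into acetyl-CoA (ENSMUSG00000020917, minus strand of chromosome 11, 100476353 to 100528000), was 5.23-fold higher (5.09 to 5.37), at 173 and 906 CPM. Acaca, the acetyl-CoA carboxylase that makes malonyl-CoA for synthesis (ENSMUSG00000020532, plus strand of chromosome 11, 84129672 to 84401651), stood at 166 and 521 CPM, a ratio of 3.15 (3.06 to 3.24). Me1, the cytosolic malic enzyme that supplies NADPH (ENSMUSG00000032418, minus strand of chromosome 9, 86581371 to 86695953), was 6.53-fold higher (6.22 to 6.86). The elongase gene Elovl6 (ENSMUSG00000041220, plus strand of chromosome 3, 129532355 to 129638495) was 2.90-fold higher (2.73 to 3.07). The desaturase gene Scd1 (ENSMUSG00000037071, minus strand of chromosome 19, 44394455 to 44407879) was the most abundant member, at 2123 and 5202 CPM, 2.45-fold higher (2.43 to 2.47). Its paralog Scd2 (ENSMUSG00000025203, plus strand of chromosome 19, 44293674 to 44306864) was 2.04-fold higher (1.94 to 2.14), and reads the paralogs share could be split between them by the counting.

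The transcription factors that drive this pathway did not move alike. Mlxipl, which encodes the glucose-responsive factor ChREBP (ENSMUSG00000005373, plus strand of chromosome 5, 135089890 to 135138382), was 2.02-fold higher (1.93 to 2.12), at 70.6 and 143 CPM. Srebf1, which encodes the insulin-responsive factor SREBP1 (ENSMUSG00000020538, minus strand of chromosome 11, 60199089 to 60222581), stood at 95.6 and 90.5 CPM, a ratio of 0.947 (0.902 to 0.994) and short of 1.5-fold. Thrsp, an abundant lipogenic cofactor gene, was 1.81-fold higher (1.79 to 1.83). Further members with values named after they were seen were Slc25a1, the mitochondrial citrate carrier (2.98-fold higher), and Acss2, which activates acetate (2.65-fold higher). The 6 members short of the size rule, Srebf1 apart also named afterwards, were Srebf1, Acacb (159 and 162 CPM), Aacs, Fads1, Fads2 and Elovl5.

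Markers of white adipocytes were also higher in the cold-recovered section. The 7 markers together stood at 308 and 685 CPM, with a median log2 ratio of 1.03 (0.96 to 1.10), and 4 of them were higher by size and none lower. Retn, the adipokine resistin, was 5.60-fold higher (5.35 to 5.85) and Nnat 2.05-fold higher (1.95 to 2.15), while Lep, the leptin gene, stood at 75.8 and 97.8 CPM. In a comparison added after the data were seen, limited to the 805 and 139 spots with at most 0.02% of UMIs from the white adipocyte list and outside muscle and lymphocyte-rich spots (the spots poor in white markers), the white list's median was 0.17. There the lipogenesis list had a median of 0.88, 11 of 18 members were higher by size and none lower, and its sum was 2.68-fold higher. Me1 had a log2 ratio of 1.996 in those spots against 2.71 over all spots and Scd2 0.25 against 1.03. Of the markers that chose these spots, Nnat had -0.09 there against 1.03, while Retn was 5.07-fold higher there.

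Thermogenic transcripts differed little as a group. The 17 measured of 20 thermogenesis genes had a median log2 ratio of -0.02 (-0.14 to 0.01), at the 34.4th percentile of random lists, and other scalings of the libraries put it at 0.01 and 0.02. Of these, 2 were higher by size, 2 lower and 13 neither, and their sum was 10283 CPM at thermoneutrality and 9517 CPM after cold. Ucp1, the uncoupling protein of brown fat mitochondria (ENSMUSG00000031710, plus strand of chromosome 8, 83290352 to 83298452), stood at 1341 and 1096 CPM, 1.22-fold lower (1.21 to 1.24) in the cold-recovered section. Cidea, a lipid droplet protein gene typical of brown fat, stood at 2723 and 2320 CPM, and Cox8b at 3171 and 3220 CPM. Adrb3, the beta-3 adrenergic receptor through which noradrenaline acts on adipocytes (ENSMUSG00000031489, minus strand of chromosome 8, 27225776 to 27250616), was 3.32-fold higher (3.08 to 3.59) from 23.6 CPM, and the coactivator gene Ppargc1b was 2.04-fold higher (1.84 to 2.26). The 2 members lower by size, named after their values were seen, were Dio2, which activates thyroid hormone (2.59 and 1.45 CPM), and Prdm16, a brown fat transcription factor gene (6.87 and 4.53 CPM). Without muscle and lymphocyte-rich spots 1 member was lower by size, and in the spots poor in white markers none. In the latter spots Ucp1 stood at 1517 and 1438 CPM, and Adrb3 was 2.30-fold higher (1.93 to 2.74).

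**Figure D1:**
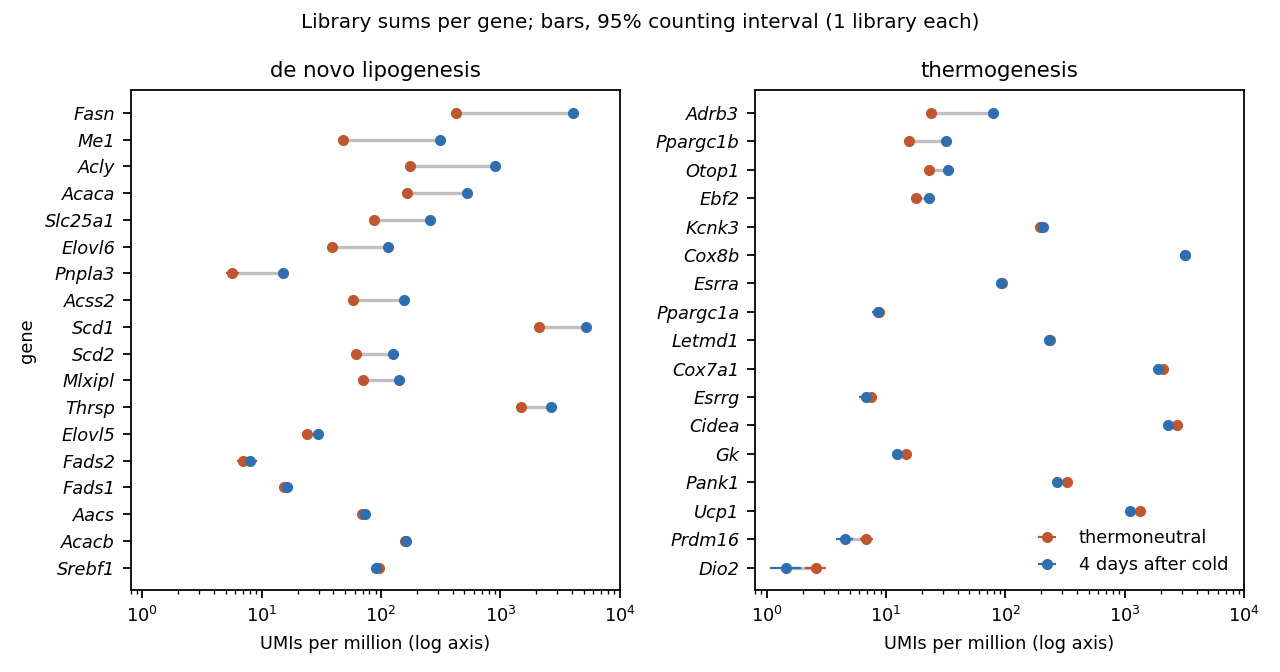
CPM (log axis) of each measured gene of the lipogenesis list (left) and the thermogenesis list (right), summed over all spots of the thermoneutral and the cold-recovered library, with exact 95% counting intervals that are mostly narrower than the points. Of the 18 lipogenesis genes 12 were higher by size after cold, and of the 17 thermogenesis genes 2 were higher and 2 lower.

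Mitochondrial transcripts showed small ratios. The 70 nuclear-encoded respiratory chain genes had a median log2 ratio of 0.10 (0.09 to 0.10), with 63 above 0 but only Atp5g1 past 1.5-fold, and Atp5g1 stood at -0.04 once muscle and lymphocyte-rich spots were left out. None of the 13 mitochondrially encoded genes (median 0.02) or the 17 genes of the tricarboxylic acid cycle (median 0.09) passed the size rule. Fatty acid oxidation genes had a median of -0.03 over 20 members, with 1 higher by size and 1 lower. Among them Cpt1a, the carnitine palmitoyltransferase isoform best known from liver, was 1.99-fold lower (1.66 to 2.38) from 10.8 CPM, and its log2 ratio was -1.66 in the spots poor in white markers against -0.99 over all spots. Genes of branched-chain amino acid breakdown had a median of 0.19 (0.16 to 0.21), at the 98.6th percentile, with none of 14 past 1.5-fold.

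Glucose and glycogen genes were higher as groups. Over 18 genes of glucose uptake and glycolysis the median log2 ratio was 0.39 (0.37 to 0.40), at the 100th percentile, with 6 higher by size and 1 lower. Eno1, an enolase gene, was 1.90-fold higher (1.87 to 1.94), Ldha 1.54-fold higher (1.52 to 1.57) and Gapdh 1.505-fold higher (1.49 to 1.52), while the hexokinase gene Hk1 was 2.27-fold lower (1.98 to 2.61). In the spots poor in white markers the log2 ratios of Ldha and Gapdh were 0.55 and 0.54, short of the rule, and 5 members were higher and 2 lower both there and without muscle and lymphocyte-rich spots. Of 13 glycogen genes (median 0.34, 0.30 to 0.44) 3 were higher and 1 lower, led by Pygl, a glycogen phosphorylase gene, at 144 and 390 CPM. Cholesterol synthesis genes had a median of 0.33 (0.19 to 0.37), with 3 of 18 higher and 1 lower. Sc5d, a sterol desaturase gene, was 2.19-fold higher (2.01 to 2.39), and in the spots poor in white markers the list's median was -0.02.

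Genes that store, take up and release fat went both ways. Triglyceride synthesis had a median log2 ratio of 0.04 (0.01 to 0.14) over 12 genes, of which 1 was higher and 2 lower, and Dgat2, which adds the last acyl chain, was 1.62-fold lower (1.60 to 1.64). Among 14 genes of lipolysis and the lipid droplet (median 0.23, 0.16 to 0.28, with 1 higher and 2 lower) G0s2, an inhibitor of adipose triglyceride lipase (ENSMUSG00000009633, minus strand of chromosome 1, 193272161 to 193273217), was 5.53-fold lower (5.31 to 5.75), at 478 and 86.5 CPM. Cidec was 1.63-fold lower (1.60 to 1.67), while the lipase genes Pnpla2 (2060 and 2045 CPM) and Lipe (502 and 536 CPM) were short of the rule. Fitm1 was 2.16-fold higher (1.95 to 2.39) over the whole section and had a log2 ratio of -0.98 without muscle and lymphocyte-rich spots. Fatty acid uptake genes (median -0.03, 13 genes, with 1 higher and 3 lower) included Angptl4, an inhibitor of lipoprotein lipase, 2.25-fold higher (2.20 to 2.30), and Fabp3, 1.67-fold lower (1.65 to 1.69). The general adipocyte list had a median of 0.28 (0.24 to 0.31), with 3 of 12 higher and none lower, among them Cfd, the adipsin gene, 1.56-fold higher (1.54 to 1.57), whereas Adipoq stood at 888.5 and 1018 CPM.

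**Figure D2:**
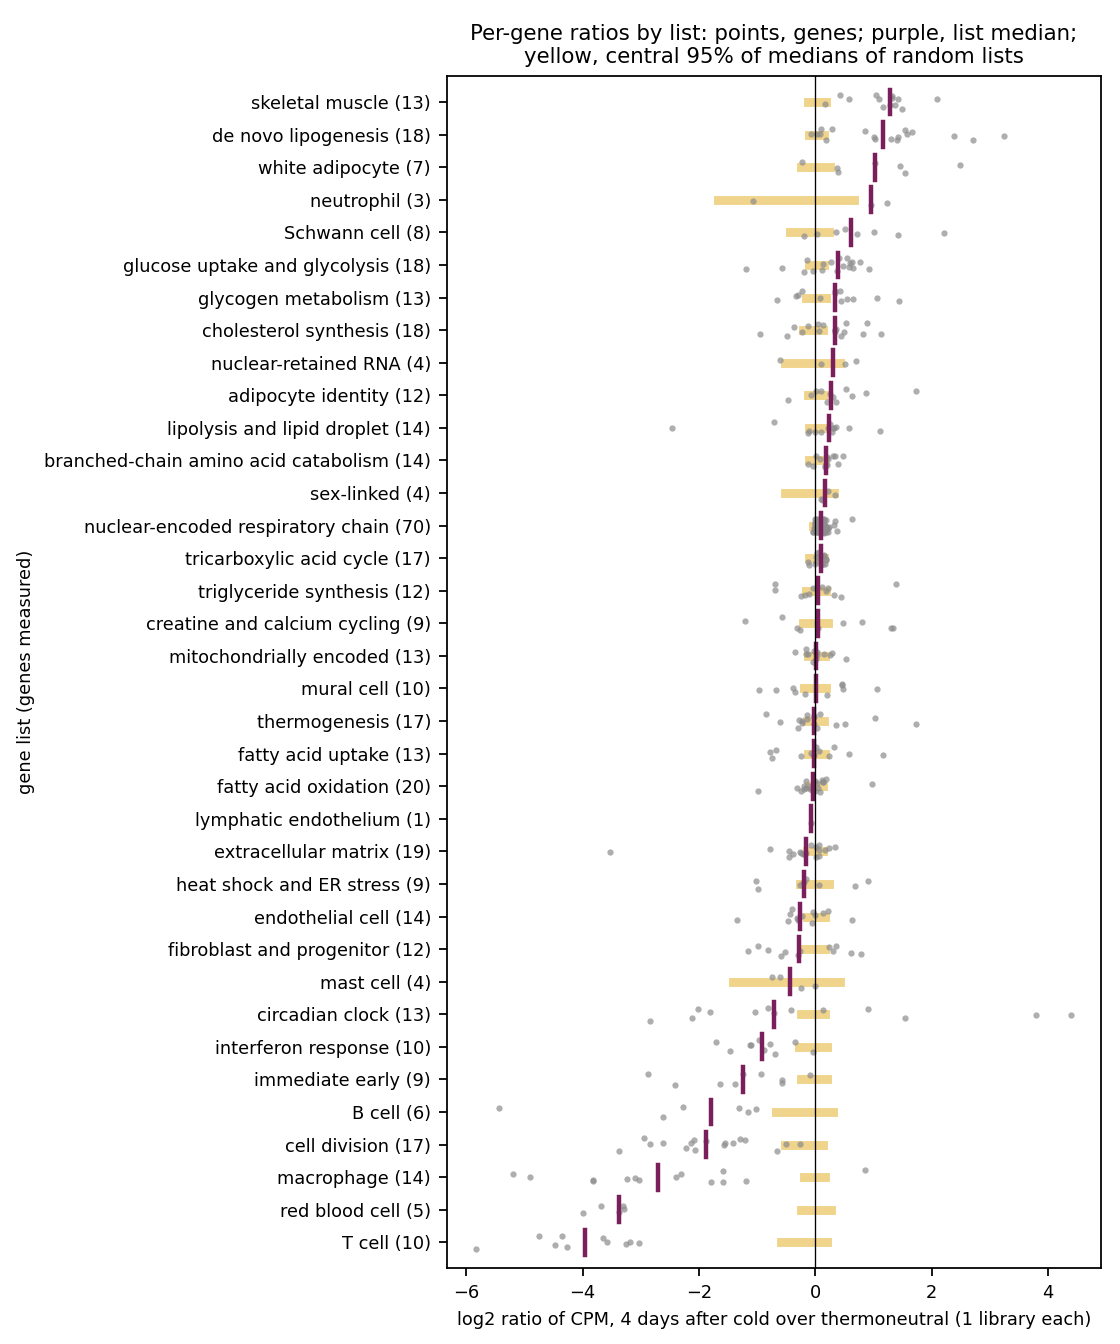
Log2 ratio of CPM, cold-recovered over thermoneutral, for each measured gene (points) of the 36 gene lists with a measured member, with the list median (purple) and the central 95% of medians of random lists matched on expression (yellow). The lipogenesis median was 1.16 and the macrophage median -2.71.

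Macrophage, T cell and B cell transcripts were far lower in the cold-recovered section. Macrophage markers summed to 1564 CPM (1552 to 1576) at thermoneutrality and 167 CPM (163 to 172) after cold, 9.36-fold lower, and 13 of the 14 markers were lower by size. The exception, Cd163, had a log2 ratio of 0.86 and was named after its values were seen. The list's median log2 ratio was -2.71 (-2.78 to -2.59), at percentile 0 of the random lists. Lyz2, the lysozyme of macrophages and other myeloid cells (ENSMUSG00000069516, minus strand of chromosome 10, 117277331 to 117282321), was 14.2-fold lower (13.5 to 14.9), at 755 and 53.3 CPM. Trem2, a lipid-sensing receptor, was 36.6-fold lower (22.7 to 63.2), and Gpnmb, a gene of lipid-laden macrophages, was 29.9-fold lower (23.8 to 38.1). Mmp12, the macrophage elastase, had 4390 UMIs at thermoneutrality and 1 after cold, and its ratio lay between 623 and 1.37e+05. The log2 ratio of Gpnmb was -4.90 over the summed spots, -4.26 with each spot weighted alike and -5.89 in the spots poor in white markers. That of Mmp12 was -11.76, or -9.63 with each spot weighted alike, and in the spots poor in white markers Mmp12 had 2178 and 0 UMIs. Red blood cell transcripts were lower with them, 10.3-fold as a sum.

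Lymphocyte markers followed the same direction. All 10 T cell markers were lower by size, with a median log2 ratio of -3.96 (-4.39 to -3.51). In the spots poor in white markers, where Il7r had 101 and 0 UMIs and was entered at a floor of 3 counts, the median was -3.16. The sum of the 10 was 14.0-fold lower over all spots and 14.7-fold lower in those spots. Trbc2, a T cell receptor chain, was 12.6-fold lower (9.23 to 17.7), and Il7r had 215 UMIs at thermoneutrality and 0 after cold, at least 45.7-fold lower by the limit of its exact interval (56.7-fold against a floor of 3 counts per library). All 6 measured B cell markers were lower (median -1.79, -2.13 to -1.65), a median that shifted to -1.16 with each spot weighted alike, -3.86 over members with at least 500 UMIs and -3.01 in the spots poor in white markers. The immunoglobulin light chain gene Igkc was 43.5-fold lower (34.3 to 56.1) with a log2 ratio of -5.44, and -4.24 without the muscle spots and the 6 lymphocyte-rich spots of the thermoneutral section and -3.92 in the spots poor in white markers. Of 3 measured neutrophil genes, S100a8 and S100a9 were higher and Csf3r lower, each below 5 CPM, with a list median of 0.96 (0.58 to 1.26), or 1.54 in the spots poor in white markers. Mast cell markers had a median of -0.43 over 4 genes (-0.81 to -0.06), of which 1 was lower, inside the range of the random lists.

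Blood and muscle differed between the sections as well. Red blood cell transcripts summed to 12343 CPM at thermoneutrality and 1194 CPM after cold, and all 5 were lower (median -3.38, -3.40 to -3.36). The beta-globin Hbb-bs stood at 7102 and 683 CPM, and the globin copies Hba-a1 and Hba-a2, or Hbb-bs and Hbb-bt, are alike enough for counts to be split between them. Skeletal muscle transcripts went the other way, at 4668 and 10915 CPM, with 10 of 13 higher by size and a median of 1.28 (1.251 to 1.301). Of the muscle UMIs 93.3% and 98.2% lay in the 142 and 121 spots with over 1% of UMIs from the muscle list, and outside them the list's median was -0.11. Leaving out muscle and lymphocyte-rich spots left the lipogenesis median at 1.21, with 12 higher and none lower. Creatine and calcium cycling genes, some of which are muscle genes, had a median of 0.04 over all spots, with 3 of 9 higher and 1 lower, and -0.58 in the spots poor in white markers. Without muscle and lymphocyte-rich spots 0 of the 9 were higher and 2 lower, with a median of -0.42. Among these genes Atp2a1, the calcium pump of fast muscle, was 2.46-fold higher over all spots, with a log2 ratio of 1.297 against 0.53 without muscle spots, whereas Ckb, the brain-type creatine kinase, was 2.31-fold lower (2.23 to 2.40).

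Over all spots the stromal and vascular lists had medians between -0.28 and 0.61. Endothelial markers had a median of -0.26 (-0.31 to -0.19) at the 0.12th percentile, with 1 of 14 higher (Cldn5) and 1 lower (Vwf). Vwf was 2.55-fold lower (2.06 to 3.18) in the sums and stood at a log2 ratio of 0.03 with each spot weighted alike. Mural cell markers had a median of 0.01 over 10 genes, of which 1 was higher and 2 lower, and the 1 measured lymphatic marker, Flt4, a log2 ratio of -0.07, or -0.84 in the spots poor in white markers. Fibroblast and progenitor markers split over all spots, with 4 of 12 lower and 2 higher (median -0.28, -0.44 to -0.11). Their sum went the other way, at 1407 and 1812 CPM. Without muscle and lymphocyte-rich spots 7 of 12 were lower and 1 higher, while the sum stood at 1409 and 1760 CPM. In the spots poor in white markers 8 of 11 were lower and 0 higher, with a median of -1.17 and sums of 1207 and 910 CPM. Cd34 was 2.23-fold lower (2.06 to 2.42), whereas Gsn was 1.72-fold higher (1.69 to 1.74), with a log2 ratio of -0.04 in those spots. Extracellular matrix genes had a median of -0.16 (-0.21 to -0.03), with 2 of 19 lower, Timp1 11.5-fold (7.25 to 19.5), whereas in the spots poor in white markers the median was -0.68 and 10 of 18 were lower. Schwann cell markers had a median of 0.61 (0.32 to 0.92), with 4 of 8 higher, and 0.02 in the spots poor in white markers. None of the 8 epithelial and mesothelial markers reached 50 UMIs over both libraries.

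The second question was how evenly lipogenic transcripts lay within each section. After thinning to 5000 UMIs per spot, which left out 109 and 104 shallower spots, spots of the thermoneutral section held 26.5 lipogenesis UMIs on average (SD 12.2 over 1609 spots) and spots of the cold-recovered section 85.3 (SD 40.3 over 1160 spots). The middle 80% of spots ran from 14 to 41 UMIs at thermoneutrality and from 43 to 139 after cold. The variance over the mean (Fano factor) was 5.64 and 19.0, against 0.98 and 0.96 for multinomial draws from each library's sum, and it scales with the mean. The coefficient of variation was 46.1% at thermoneutrality and 47.2% after cold, against 19.2% and 10.6% for the draws, and 42.3% and 37.7% without muscle and lymphocyte-rich spots. In the part of these spots with at most 1 white adipocyte UMI, a limit added after the data were seen, it was 33.9% and 24.0%, and the Fano factors were 2.81 and 3.97.

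Lipogenesis UMIs went with white adipocyte UMIs from spot to spot in both sections (Pearson r across spots 0.44 and 0.59), whereas thermogenesis UMIs ran against them (r -0.43 and -0.56). Lipogenesis and thermogenesis UMIs themselves had an r of 0.00 at thermoneutrality and -0.15 after cold, against -0.03 for multinomial draws in both libraries. Without muscle and lymphocyte-rich spots r was -0.16 and -0.45, and among those of the remaining spots with at most 1 white adipocyte UMI it was 0.11 and 0.28. Some pairs of lipogenic genes had a higher r after cold, for example Fasn with Acly (r 0.57 against 0.06 at thermoneutrality) and Scd1 with Me1 (0.70 against 0.21). Among the same spots with at most 1 white adipocyte UMI these were 0.29 against -0.0045 and 0.24 against 0.048, and Fasn with Scd1 had 0.25 against 0.21. Low counts pull r toward 0, and Acly and Me1 were sparse at thermoneutrality. These were 3 of 45 gene pairs computed per section.

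Outside muscle and lymphocyte-rich spots, lipogenesis was higher after cold at every level of white adipocyte transcripts. In spots without a white adipocyte UMI the mean was 23.9 lipogenesis UMIs at thermoneutrality (SD 7.49, 503 spots) and 69.0 after cold (SD 16.3, 129 spots). In spots with 16 or more it was 48.7 (SD 16.2, 32 spots) and 133 (SD 27.7, 104 spots). The ratio of the means lay between 2.72 and 2.89 over the 6 bins. Thermogenesis means in the same bins ran from 53.8 to 20.4 UMIs at thermoneutrality and from 55.2 to 22.3 after cold, with ratios between 1.03 and 1.09.

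**Figure D3:**
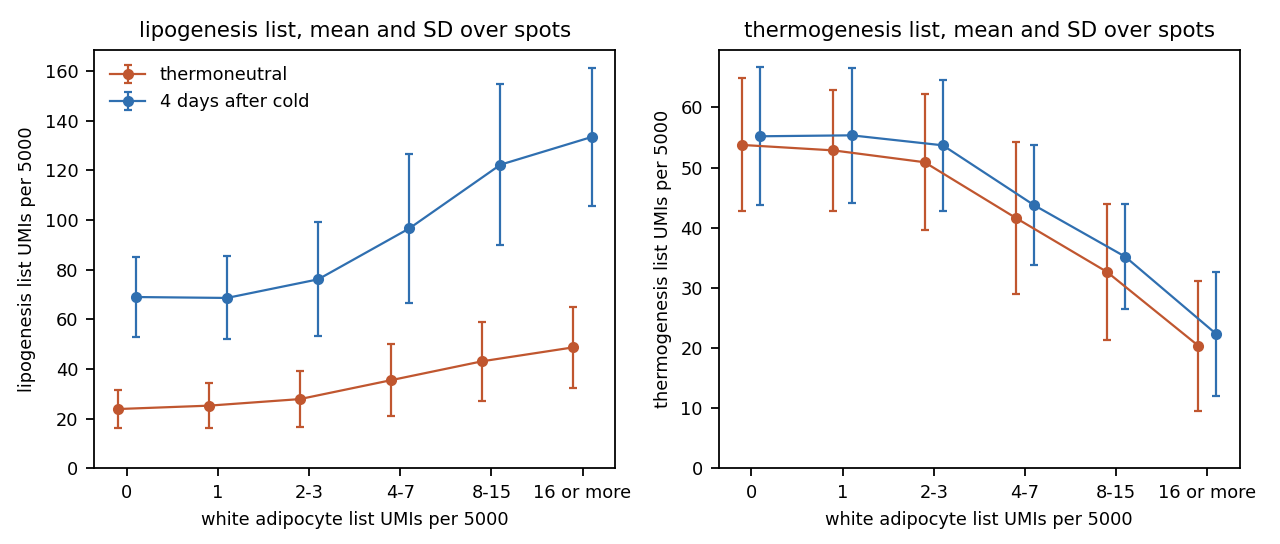
Mean lipogenesis (left) and thermogenesis (right) UMIs per spot at 5000 UMIs, by the spot's white adipocyte list UMIs, outside muscle and lymphocyte-rich spots, with bars of 1 SD over spots, which are not replicates. The lipogenesis means of the cold-recovered section were 2.72 to 2.89 times those of the thermoneutral section in each of the 6 bins.

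Over all thinned spots, the share with at least 1 UMI was higher after cold for Acly and Elovl6 and lower for Ucp1 and Lyz2. Acly was seen in 55.3% of thermoneutral spots (exact Clopper-Pearson interval 52.8 to 57.8) and 94.2% of cold-recovered spots (92.7 to 95.5) at 5000 UMIs. Unthinned, the shares were 89.5% and 97.9%, at median depths of 22682 and 23804 UMIs. Muscle spots had shares of 29.0% and 49.0% (131 and 102 spots, median depths 13048 and 22932). Muscle spots also held fat transcripts, with Fabp4 at 4099 and 2323 CPM over all 142 and 121 of them, so their shares are not background alone. Elovl6 was seen in 17.9% (16.1 to 19.9) and 44.7% (41.9 to 47.7) of spots, unthinned in 54.1% and 83.4%, with 7.63% and 18.6% in muscle spots. For Me1 the shares were 21.3% (19.3 to 23.3) and 75.1% (72.5 to 77.6), unthinned 63.1% and 97.8%, but at thermoneutrality the share lay below the 29.0% of muscle spots and is not told from background or from Me1 made in muscle. Ucp1 was seen in 96.2% (95.2 to 97.1) and 89.3% (87.4 to 91.0) of spots, unthinned in 98.6% and 94.7%, with 71.0% and 27.5% in muscle spots. Without muscle and lymphocyte-rich spots the Ucp1 shares were 98.4% and 95.3%, and 99.8% and 99.7% in those with at most 1 white adipocyte UMI. Lyz2 was seen in 86.3% (84.5 to 87.9) and 22.7% (20.3 to 25.2) of spots, unthinned in 98.8% and 61.1%, and muscle spots had 78.6% and 20.6%. After cold the muscle-spot share lay inside the interval over all spots. There the Lyz2 share is not told from background or from Lyz2 made in muscle spots.

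The third question was which regions of each section carried these transcripts. Clustering the spots of each library on its own gave 5 regions in each, described by their leading genes and not compared in size between the sections. At thermoneutrality the region led by Lncbate10, Clstn3, Kng2, Ucp1 and mt-Cytb (738 spots) held 22.6 lipogenesis UMIs per 5000 (22.4 to 22.7) and 54.7 thermogenesis UMIs. A region led by Igha, Mmp12, Gpnmb, Lyz1 and Lilrb4a (441 spots) held 29.5 lipogenesis UMIs and 15.96 macrophage UMIs (15.8 to 16.1), against 3.33 (3.27 to 3.38) in the first region. The region led by Retn, Nnat, Sncg, Trf and Ccdc80 (314 spots) held 32.5 lipogenesis UMIs (32.2 to 32.9). The region led by Jchain, Ighm, Igkc, Acta2 and Gdf10 (76 spots) held 27.5, and the muscle-led region (149 spots, led by Atp2a1 and Myh4) held 14.0.

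In the cold-recovered section the region led by Myo5b, Tusc3, Kng2, Ucp1 and Clstn3 (415 spots) held 63.4 lipogenesis UMIs per 5000 (63.1 to 63.7), 53.3 thermogenesis UMIs and 0.537 macrophage UMIs (0.511 to 0.565). The region led by Nnat, Slc25a10, Trf, Cyp2e1 and Me1 (407 spots) held 92.6 lipogenesis UMIs, and the smooth-muscle-gene region led by Acta2, Myh11, Myl9, Flna and Csrp1 (192 spots) held 87.0 with 60.7 thermogenesis UMIs. This Acta2-led region held 1371 mitochondrially encoded UMIs per 5000 against 2058 in the Ucp1-led region, which leaves a larger share for all other transcripts. The region led by Wfdc21, Slc7a10, C4b, Serpina3n and Ighm (142 spots) was highest in lipogenesis, at 141 (139.9 to 143), and low in thermogenesis, at 22.6 (22.02 to 23.14), with 20.9 white adipocyte UMIs. It also held 169.6 UMIs of the general adipocyte list, against 78.9 in the Ucp1-led region, and only 1320.5 mitochondrially encoded UMIs. Its high lipogenesis value therefore cannot be told from a larger share of adipocyte transcripts. The muscle region (108 spots, led by Tnnc2, Pvalb and Myh4) held 14.6 lipogenesis UMIs, and its thermoneutral counterpart 14.0. These muscle regions differed in adipocyte content, with 14.9 UMIs per 5000 of the general adipocyte list after cold and 39.5 at thermoneutrality. The similar lipogenesis values therefore do not show an unchanged level. Fasn stood at 663 CPM in the cold-recovered muscle region and 367 CPM in the thermoneutral one. Fasn ranged from 349.7 to 718 CPM over the 4 regions other than muscle at thermoneutrality and from 3809 to 7273 CPM after cold, and Acly from 161 to 187 and from 863 to 1466 CPM. At a Leiden resolution of 1.0 the sections split into 11 and 8 regions. Spot positions were not used here, and RNA can spread between neighbouring spots during capture, so borders between regions are blurred to an unknown degree.

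**Figure D4:**
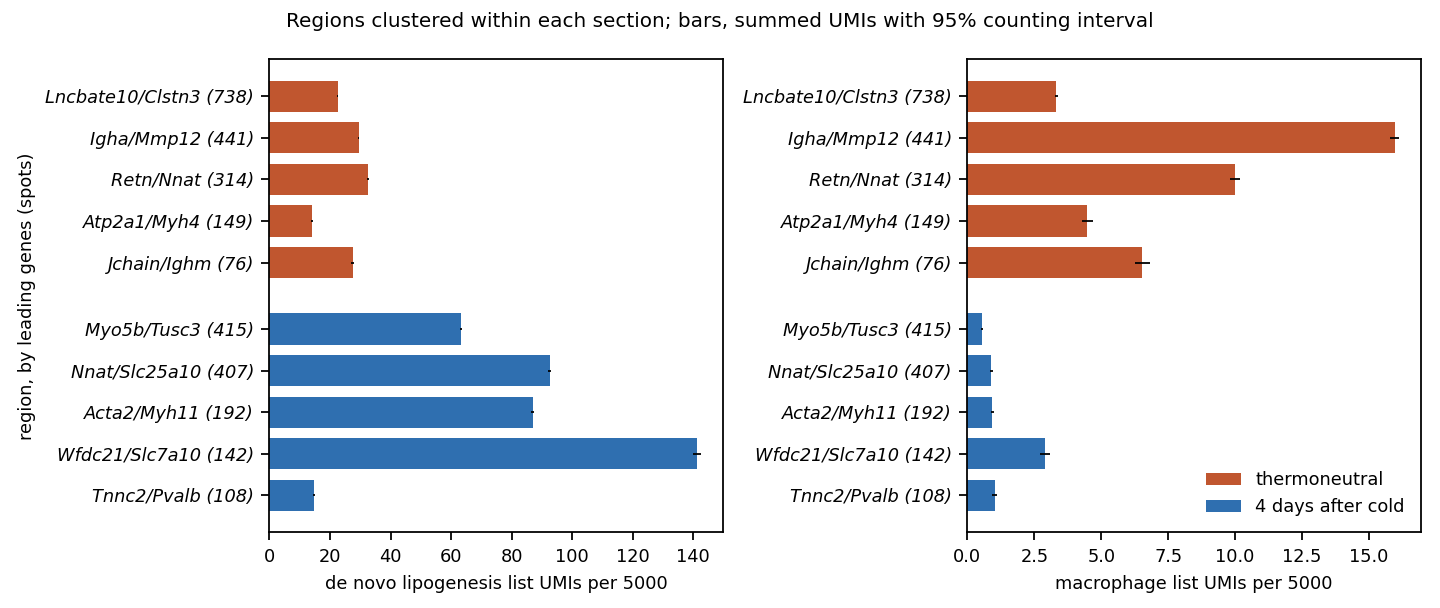
Lipogenesis (left) and macrophage (right) UMIs per 5000 in the regions clustered within the thermoneutral and the cold-recovered section, named by their first leading genes with the number of spots, with bars from 0 and exact 95% counting intervals. Regions other than muscle held 22.6 to 32.5 lipogenesis UMIs at thermoneutrality and 63.4 to 141 after cold.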

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

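The comparisons that left out spots by white adipocyte UMIs or at 0.1% muscle UMIs were chosen after the results were seen, and the others before. No paired analysis was possible because each group has 1 library. The lipogenesis median log2 ratio (1.16, interval 1.121 to 1.197) stayed above 0 in every alternative run: 1.201 with DESeq2 size factors, 1.47 with each spot weighted alike, 1.21 without muscle and lymphocyte-rich spots, 1.204 without spots of over 0.1% muscle UMIs and 0.88 without white-marker spots, while the remaining alternatives left it inside its interval. The thermogenesis median (-0.02) was 0.012 with TMM factors and 0.017 with DESeq2 size factors. The median over all measured genes lay between -0.10 and 0.01 under every setting. Of the other 34 measured lists none moved beyond its counting interval when spots under 2000 UMIs were left out. Besides those of at least 1.5-fold whose sign turned, 9 moved with TMM factors, 10 with DESeq2 size factors, 4 without mitochondrial UMIs, 20 with each spot weighted alike, 14 without muscle and lymphocyte-rich spots and 27 without white-marker spots. Of 203 named genes 59, 65, 32, 105, 80 and 143 moved in that order of settings. Shares of spots with a UMI moved with the thinning depth in 25 of 26 cases and without muscle and lymphocyte-rich spots in 8.

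Among values of at least 1.5-fold, signs turned mainly for the skeletal muscle list and for genes that muscle expresses. Without muscle and lymphocyte-rich spots the list's median was -0.11, with Des -0.0033, Ckm -0.045, Ryr1 -0.42, Tnnt3 -0.24, Myh4 -0.11, Atp5g1 -0.040 and Fitm1 -0.98. Without white-marker spots, which also leaves out muscle spots, it was -0.040, with Ckm -0.067, Ryr1 -0.086, Tnnt3 -0.65, Acta1 -0.11, Atp5g1 -0.44 and Fitm1 -1.14, and Gsn (-0.043) and Nnat (-0.094) turned as well. Fitm1 was -0.66 without spots of over 0.1% muscle UMIs. Vwf was 0.028 with each spot weighted alike, and the cause was not tested. Smaller values turned too and count as moved above, among them the creatine and calcium cycling list (-0.42) and Atp2a2 (-0.27) without muscle and lymphocyte-rich spots. Without white-marker spots the lists of creatine and calcium cycling (-0.58), nuclear-retained RNA (-0.71) and cholesterol synthesis (-0.025) turned, as did Dpt (-0.52), Malat1 (-0.71) and Acta2 (-0.19), again among others. The cell division median (-1.89) was -0.65 over the members with at least 500 UMIs, a limit that leaves fewer genes.

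The Fano factor of lipogenesis UMIs scales with depth by construction. At thermoneutrality it was 2.89 at 2000 UMIs and 9.73 at 10000, 4.90 without muscle and lymphocyte-rich spots and 2.81 in those left with at most 1 white adipocyte UMI. After cold the values were 8.41, 35.2, 12.8 and 3.97. The r of lipogenesis with thermogenesis at thermoneutrality (0.00) was 0.12 at 10000 UMIs, -0.16 without muscle and lymphocyte-rich spots and 0.11 in those left with at most 1 white adipocyte UMI. After cold (-0.15) it was -0.071, -0.45 and 0.28, so its sign depended on which spots entered. The 5 regions per section became 11 and 8 at a resolution of 1.0, 4 and 4 at 0.3, and 7 and 6 with 15 principal components. Depth limits genes of a few UMIs: 1 UMI was worth 0.0249 CPM at thermoneutrality and 0.0314 CPM after cold.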

Other observations

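The tests of explanations in this part were all chosen after the results were seen, while the gene lists were fixed before. Clock genes differed strongly between the sections. Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, plus strand of chromosome 7, 113207465 to 113314126 in mm10), had 22 UMIs at thermoneutrality and 241 after cold, 13.8-fold higher (8.93 to 22.5), and Npas2, which encodes a paralog of its partner CLOCK, had 0 and 50 UMIs, at least 16.5-fold higher by the limit of its exact interval (21.1-fold against a floor of 3 counts per library). Some genes that peak at the opposite phase were lower, among them Dbp, 4.06-fold (3.82 to 4.32), and Per2 and Per3, named after their values were seen, with log2 ratios of -2.84 and -1.80. Nr1d1, which encodes REV-ERB alpha, was 2.91-fold higher (2.75 to 3.08). Over 13 clock genes 4 were higher by size, 7 lower and 2 neither, with a median of -0.70 (-0.81 to -0.52). Within muscle spots Arntl went from 1 to 42 UMIs and Dbp from 349 to 137, while Npas2 had 0 and 3 UMIs and Tef 303 and 327 (log2 ratio -0.36).

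Cell division and interferon-response lists were lower after cold by their medians, with sums only 1.98-fold and 1.12-fold lower. Macrophage and T cell markers were lower too, with sums 9.36-fold and 14.0-fold lower. Which cells the cell division and interferon-response transcripts came from was not resolved. Of 17 measured cell division genes 15 were lower by size and none higher (median -1.89, -2.10 to -1.51), with Mki67 7.72-fold lower (4.86 to 12.9) from 4.85 CPM, and the median was -0.65 over the members with at least 500 UMIs. Interferon-response genes were lower in 8 of 10 cases (median -0.92, -1.03 to -0.82), such as Ifit3, 3.26-fold (2.73 to 3.92), and the exceptions included the abundant Ifi27 at 1274 and 1246 CPM. Of 9 immediate early genes 6 were lower (median -1.24, -1.36 to -1.10), with Egr1 5.30-fold lower (4.63 to 6.09), whereas Jun stood at 54.2 and 51.1 CPM. Cd74 stood at 598 and 80.6 CPM and H2-Ab1, of a family whose members can share reads, at 328 and 43.0 CPM, both antigen presentation genes named after their values were seen. Chemokine genes Ccl8 (32.1-fold, 25.2 to 41.3) and Ccl5 (17.8-fold, 15.1 to 21.3) were among the 12 lowest genes, and Ccl8 had a log2 ratio of -5.00, or -4.17 with each spot weighted alike. Of the 12 highest genes 6 were slow-muscle genes, led by Tnnc1 at 8.51 and 83.0 CPM and Myh7 at 21.5 and 204 CPM. Within muscle spots Myh7 stood at 444 and 2446 CPM and Myh4, a fast-fibre gene, at 10820 and 15320 CPM, and without muscle spots the log2 ratios of Tnnc1 and Myh7 were 1.99 and 1.58 against 3.29 and 3.24. Depp1, a FOXO target, was 6.50-fold higher (6.08 to 6.94). Heat shock and ER stress genes had a median of -0.19 (9 genes, 2 higher and 2 lower), and 4 nuclear-retained RNAs had 0.30, or -0.71 in the spots poor in white markers. The 4 measured sex-linked genes were Y-linked, present in both libraries, and none passed 1.5-fold (median 0.17). In the spots poor in white markers the log2 ratios of Arntl, Mki67 and Ifit3 were 2.79, -4.37 and -2.65, against 3.79, -2.95 and -1.70 over all spots, and Npas2 had 0 and 8 UMIs, at least 8.24-fold higher by its exact interval.

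Higher lipogenesis in the cold-recovered section was weighed against more white fat in that section and against the time of day. In spots without a white adipocyte UMI, outside muscle and lymphocyte-rich spots, the ratio of lipogenesis UMIs was 2.89. This argues against white tissue as the whole cause. However, all 7 white markers also reached 1 CPM in the 25% of cold-recovered spots richest in Ucp1, led by Lep (100.3 CPM) and Retn (81.5 CPM). Lep was no lower there than over the whole section, so the white list does not mark white tissue alone. A difference in clock phase remains open. The clock arms compared were Arntl, Npas2 and Clock against Dbp, Tef, Per1, Per2, Per3 and Ciart. Nr1d1, with log2 ratios of 1.54 over the section and 2.04 in muscle spots, was left out, as were Nr1d2, Cry1 and Cry2. The medians of the arms lay 5.70 log2 units apart over the section and 3.53 in muscle spots, where Clock had 9 and 40 UMIs. Since each condition was sampled once, phase and earlier cold cannot be told apart as sources of the lipogenic difference. An effect of the earlier cold stays a hypothesis, untested here.

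Lower macrophage transcripts after cold were weighed against blood left in the thermoneutral section and against macrophage-rich patches that this section alone contained. At the same 8 to 15 haemoglobin UMIs per spot, macrophage UMIs were 9.23 times higher at thermoneutrality (11.6 on average, SD 14.9, 127 spots, against 1.253, SD 1.58, 190 spots), which argues against blood as the whole cause. In the region of each section with Ucp1 among its 5 leading genes they were 6.19 times higher (3.33 against 0.537 per 5000; the Acta2-led region after cold, higher in Ucp1, held 0.934), which argues against patches as the whole cause, although RNA that spread from patches to other spots may have raised the first value. No macrophage or red blood cell marker is shared with another list, and Lyz2 was at 505 and 47.8 CPM in the 25% of spots richest in Ucp1. An effect of the earlier cold, or of the individual mouse, stays untested.

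The inverse relation of lipogenesis and thermogenesis UMIs across the cold-recovered section (r -0.15 over all spots) was weighed against a gradient of white adipocyte transcripts. Without muscle and lymphocyte-rich spots r was -0.45, and in those left with at most 1 white adipocyte UMI it was 0.28. From the lowest to the highest of 6 bins of white adipocyte UMIs r was 0.31, 0.26, -0.02, -0.08, -0.13 and 0.41. In the lowest bin mitochondrially encoded UMIs averaged 1865 per thinned spot (SD 417). At a fixed depth such variation moves both lists in the same direction and pushes r upward. A mixture of white-marker-rich and Ucp1-rich tissue therefore stays possible. How much of the negative relation it accounts for cannot be told from these r values. Whether lipogenic and thermogenic transcripts sit in the same or in separate brown adipocytes was not tested, because a spot holds several cells.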
